A study of Mus musculus with 4 samples.

How the data were processed

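The series holds 4 droplet libraries of mouse cells sorted from TC-1 tumours, which grow from a transplanted mouse lung epithelial tumour cell line. Per the labels' protocols, wild-type mice received 300000 TC-1 cells under the skin, and PBS or 1 intraperitoneal dose of cisplatin (6 mg/kg) was given once the tumour reached 40 mm². One library comes from the PBS group and 1 each from tumours collected 1, 3 and 7 days after cisplatin. The labels give no day for the PBS library, call its source untreated in 1 field while the treatment field says PBS, and do not say how many mice each library pools. The sorted cells were defined as CD45+, lineage-negative, CD90+ and CD127+, a gate for innate lymphoid cells (ILCs), and 15000 cells per library were loaded for 10x 3' version 3 chemistry, with a stated depth of 20000 reads per cell.

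The deposited values are raw UMI counts per gene and barcode. Per the file headers they are whole numbers written by software version 3.1.0. The submitters' processing notes name Cell Ranger 3.1.0 and the build mm10, and also Seurat 3.1.2, whose role is not stated. All 31053 features of the 4 tables share the same order, and every deposited barcode of the PBS, day 1 and day 3 libraries holds at least 500 UMIs, with a lowest value of 507 on day 7. Gene positions were taken by Ensembl identifier from an mm10 annotation (GENCODE vM21), and 581 of the 581 named genes had one.

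Barcodes were kept with at least 500 genes and at most 10% mitochondrial counts. Doublets were to be removed at Scrublet's automatic threshold, but with an expected rate of 8% this marked only 4, 4, 0 and 0 cells in the PBS, day 1, day 3 and day 7 libraries, so the caller has not worked. In its place the cells with the highest Scrublet scores were removed at 0.8% per 1000 barcodes of each library, a choice made after seeing the data, which took out 650, 643, 249 and 66 cells. The 21686 kept cells of the 4 libraries were clustered together on log-normalised counts without batch correction (2000 variable genes, 30 principal components, 20 neighbours, Leiden at resolution 1), giving 24 clusters.

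Clusters were named from 14 marker lists fixed before the data were examined. The limits of the naming rule were set after the clusters had been seen, because markers ranked against the rest do not mark a class that makes up most cells. A cluster is macrophage-like when on average at least 65% of its cells hold a given macrophage marker and no other class has 6 markers at 3-fold or more. Any other name needs 4 markers of its class at 3-fold or more, each in 10% of the cells with 20 UMIs, and at least 1 of them among the 10 leading genes. ILC names were barred where 6 markers of a T cell list passed. A class in which the leading 10 genes of any cluster hold more markers of another class was compared between libraries by cluster number only. The macrophage-like and alpha-beta T-like classes are of this kind, so their planned shares per library serve only as sums of clusters, while pooled over libraries they are set beside other classes.

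Each group is 1 library. No test, p-value, standard error or count of changed genes was therefore made, and cells were not treated as replicates. Shares carry exact Clopper-Pearson 95% intervals, and ratios of summed counts scaled to the library total (CPM) carry the exact conditional binomial 95% interval. Both cover counting error only, not variation between mice, tumours or sorts. The 3 comparisons use the same PBS library, so an unusual PBS value enters all of them, and no correlation between days is given. Where 1 library has no count of a gene, the ratio was computed against a floor of 3 counts and is a bound. Gene lists (23, fixed before the data were examined) are summarised by the median log2 ratio of members with at least 20 UMIs over the 2 libraries, and by its percentile among 10000 random lists matched on mean expression. The interval of a list median is the binomial interval of order statistics over its members. It describes the spread of members, not replication. Members count as higher or lower when they differ by at least 1.5-fold with an interval that excludes 1. Of the fixed symbols, Mx2, Il26, Cxcl11, Hn1 and Aldoa are missing from the features.

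The genes named were chosen by a rule written before the data were examined. It takes 21 lineage, effector, sort gate and p53 genes in every comparison, the 12 highest and 12 lowest genes by the bound of the ratio nearer to 1 among genes with at least 50 UMIs (leaving out Gm and Rik gene models, mitochondrial and ribosomal protein genes and receptor segments), and up to 4 members of each list with the largest log2 ratios. In clusters 9, 0 and 5 the list members were not named. Some genes that the rule takes are not reported here. Comparisons ran over all kept cells and within the group 1 ILC-like cluster 15, the only ILC class found with at least 50 cells in every library. Clusters 0, 5 and 9, which also have at least 50 cells in all 4 libraries, were added after seeing the data. Shares of cells with a UMI were computed after thinning every cell to 2000 UMIs and leaving out shallower cells. A cell counted as cycling with at least 3 UMIs of the S and G2M lists after thinning.

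The ratio and list steps were tested on simulated summed counts with 200 genes changed by known folds. These were drawn as Poisson counts, so interval coverage near 95% follows from the setting. Variation between cells or mice, clustering, doublets and free RNA were not simulated. For the day 1, day 3 and day 7 comparisons over all kept cells (31053 genes simulated), 2-fold differences were recovered for 100%, 95.9% and 91.3% of such genes, and in cluster 15 for 80.6%, 77.2% and 90.3%. For 1.5-fold differences these shares were 91.0%, 98.4% and 89.0%, and 59.7%, 48.6% and 42.6% in cluster 15. Recovered here means an interval that excludes 1 in the true direction, for genes with at least 50 UMIs. The counts of list members also need a ratio of at least 1.5-fold and admit members from 20 UMIs. Their sensitivity was therefore not measured, and the low shares in cluster 15 limit its counts of members. Intervals of unchanged genes covered no difference for 95.6%, 95.5% and 95.7% of them over all kept cells, and for 96.2%, 95.6% and 96.2% in cluster 15. Alternatives were other Leiden resolutions, each library clustered alone, clustering without cell state genes, stricter and absent cell filters, doublets kept, a class per cell, TMM and DESeq2 scaling, per-cell means, thinned cells and other count minimums. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.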

Results

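The study collected single-cell transcriptomes of cells sorted from TC-1 tumours as innate lymphoid cells, the tissue lymphocytes that lack antigen receptors. One library followed PBS, and 1 library each was taken 1, 3 and 7 days after a dose of cisplatin, a platinum drug that damages DNA. The PBS, day 1, day 3 and day 7 libraries hold 10063, 10745, 6264 and 2981 barcodes, where 15000 cells were loaded for each. Their total counts are 59915831, 82493626, 36587207 and 16153484 UMIs, and 7425, 6841, 4715 and 2705 cells were kept. The median depth of kept cells was 6162, 8769, 6045 and 5039 UMIs. Each group has 1 library and no replicate check, so all intervals below are counting error only, and day, tumour age, sort and library batch cannot be told apart from treatment.

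Most of the sorted cells were not lymphocytes by their transcripts. Macrophage-like cells, which expressed Lyz2, Apoe and the complement genes C1qa, C1qb and C1qc, filled 14 of the 24 clusters and between 74.5% and 91.7% of the kept cells of each library. T-like cells formed clusters 9, 10 and 13. Cluster 9 was led by Foxp3, Ctla4 and Ikzf2, genes of regulatory T cells, cluster 10 by Cd8a, Cd8b1 and granzymes of cytotoxic T cells, and cluster 13, which was gamma-delta T-like, by Cd163l1, Trdc and Il17a. Cluster 15 was group 1 ILC-like, the class that joins natural killer (NK) cells and ILC1, with Ncr1, Klrb1c, Klra8, Prf1 and Gzma in front. Small clusters were dendritic-cell-like (20, with Fscn1, Ccr7 and Ccl22), mast-cell-like (22, with Mcpt4, Cma1 and Cpa3) and endothelial-like (23, with Gpihbp1 and Plvap). Clusters 18, 19 and 21 stayed unnamed. No cluster was ILC2-like or ILC3-like.

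Transcripts of the sort gate lay in lymphoid clusters and also in other cells. Thy1 encodes CD90, Il7r encodes CD127 and Ptprc encodes CD45. After thinning to 2000 UMIs, Thy1 was detected in 39.4% of group 1 ILC-like cells (34.8 to 44.1%; 61.8% unthinned), with 68 shallower cells left out, and in 35.3% of alpha-beta T-like cells, with 478 left out. In macrophage-like cells the share was 0.930% (0.789 to 1.09%; 3.60% unthinned), with 1261 left out. In the 80 thinned cells of the mast-cell-like cluster it was 1.25% (0.0316 to 6.77%). Cluster 18, which stayed unnamed and is led by Meg3 and collagen genes, had Thy1 in 19.5% of cells. Il7r was found in 64.2% of gamma-delta T-like cells, in 49.7% of alpha-beta T-like cells and in 7.09% of group 1 ILC-like cells, beside 6.01% of macrophage-like cells. In the day 3 library alone these last shares were 9.45% (4.98 to 15.9%) and 13.6% (12.5 to 14.9%). Il7r was also frequent in dendritic-cell-like cells, at 68.1%, and was found in 17.5% of mast-cell-like cells (9.91 to 27.6%) and in 0 of 229 thinned cells of cluster 19. Ptprc was detected in 49.8% of macrophage-like cells. The median depths were 5135 UMIs in group 1 ILC-like cells, 3335.5 in alpha-beta T-like cells, 6843 in macrophage-like cells and 3533 in mast-cell-like cells. In the other direction, Lyz2 was detected in 85.8% of alpha-beta T-like cells and in 86.7% of group 1 ILC-like cells.

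**Figure D1:**
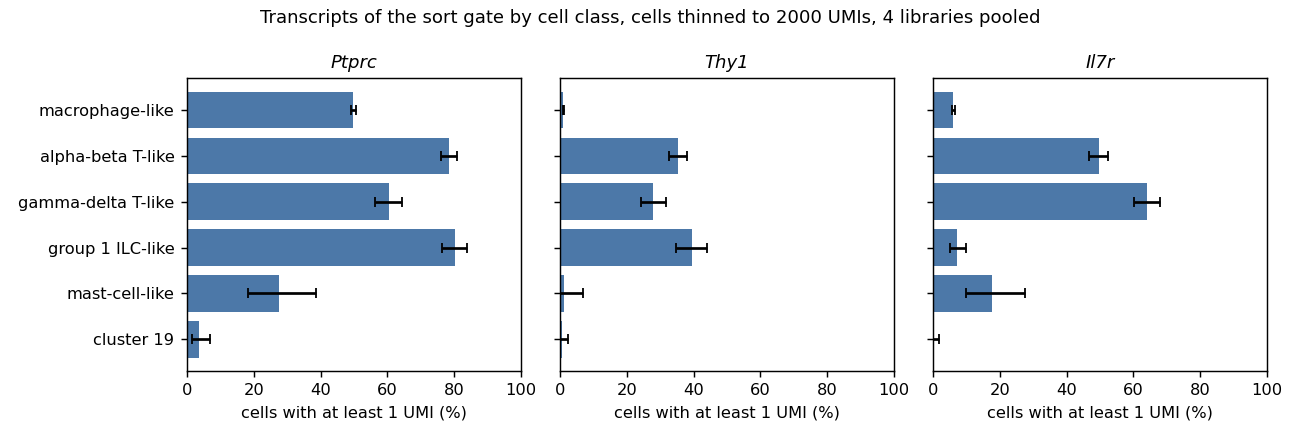
Share of cells with at least 1 UMI of Ptprc, Thy1 or Il7r (x axis, percent) in each cell class (y axis), with the 4 libraries pooled and cells thinned to 2000 UMIs. Error bars are exact 95% intervals. Thy1 lies at 39.4% in the group 1 ILC-like class and at 0.930% in the macrophage-like class.

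The 4 libraries differed in which cells they held, and the sort gate and its yield can set these shares. The Foxp3-led cluster 9 made up 1.64% of kept cells in the PBS library (1.37 to 1.96%), 5.93% on day 1 (5.39 to 6.52%), 5.81% on day 3 (5.16 to 6.52%) and 2.00% on day 7 (1.503 to 2.60%). The Cd8a-led cluster 10 held 0.552%, 4.66%, 8.65% and 2.29%, and the gamma-delta T-like cluster 13 held 1.55%, 4.33%, 4.75% and 1.18%. Many of these barcodes also held macrophage RNA. More than 1% of UMIs came from macrophage markers in 40.0%, 68.6%, 38.4% and 39.8% of T-like and group 1 ILC-like cells. In cluster 13 this share was 64.2% over all libraries. Pooled T-like and group 1 ILC-like cells above 1% had a median doublet score of 0.137, against 0.0347 in the others. Leftover doublets may therefore enter these shares. With each library clustered on its own, T-like cells were 5.91% on day 1 and 6.73% on day 7, while the sums of clusters 9, 10 and 13 are 14.9% and 5.47%. On day 3 the sum of 19.2% became 9.99%, and at Leiden resolution 0.5 the day 3 share of 10.8% lay below the day 1 share of 12.4%. Group 1 ILC-like cells were 1.24% in the PBS library (1.00 to 1.52%), 2.22% on day 1 (1.89 to 2.60%), 2.86% on day 3 (2.41 to 3.38%) and 4.66% on day 7 (3.89 to 5.52%), all of them in cluster 15. Among T-like and group 1 ILC-like cells alone, cluster 15 held 24.9%, 12.96%, 12.97% and 46.0%, so its order between the days depends on the denominator. The dendritic-cell-like cluster held 0.364%, 1.46%, 1.97% and 0.0739%. Mast-cell-like cells were 0.350%, 0.833% and 0.276% of the PBS, day 1 and day 3 libraries and were found in 0 of 2705 cells on day 7.

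**Figure D2:**
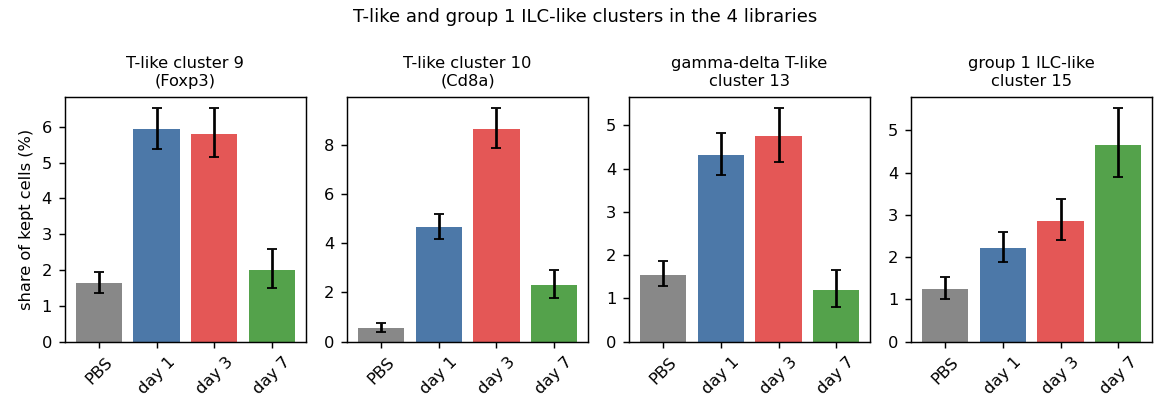
Share of kept cells (y axis, percent) in clusters 9, 10, 13 and 15, for the PBS, day 1, day 3 and day 7 libraries. Error bars are exact 95% intervals over cells. Cluster 10 stands at 0.552% in the PBS library and 8.65% in the day 3 library.

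Each library had its own main macrophage-like cluster. With 1 library per group, a cluster mostly of 1 library may be that library, not a type, and macrophages are compared between libraries by cluster number because the leading genes of clusters 3, 5 and 11 hold more markers of another class. In the PBS library cluster 0 (Hpgd, Fcrls, Cx3cr1) held 33.7% of macrophage-like cells (32.6 to 34.9%), clusters 6 and 14, with the cell cycle genes Birc5 and Cdca3 among their leading genes, held 13.1% and 6.29%, and cluster 16, led by Lpl, held 4.98%. Cluster 14 held 7.60% (6.54 to 8.77%) on day 7. On day 1 the largest were cluster 4 with 22.5% (Cd163, Stab1, Folr2, genes of tissue-resident macrophages), cluster 1 with 20.4% (Arg1, Cxcl3, Clec4e) and cluster 8 with 14.9% (Gdf15, Mertk, Plau). On day 3 cluster 2, led by Slfn4, Rsad2, Chil3 and other interferon-induced or monocyte genes, held 46.9% (45.2 to 48.5%), beside 0.735% in the PBS library. Cluster 11, with Nos2, Cxcl9, Acod1 and H2-Ab1, held 13.5% on day 3 and 0.749% in the PBS library. On day 7 cluster 3 held 73.0% (71.1 to 74.8%) and was almost absent elsewhere, since 99.3% of its cells came from that library. Its leading genes were haemoglobins with Prune2 and Slc39a1. Without thinning, Hba-a1 was found in only 1.41% of the day 7 macrophage-like cells, so few cells carry these haemoglobin counts.

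**Figure D3:**
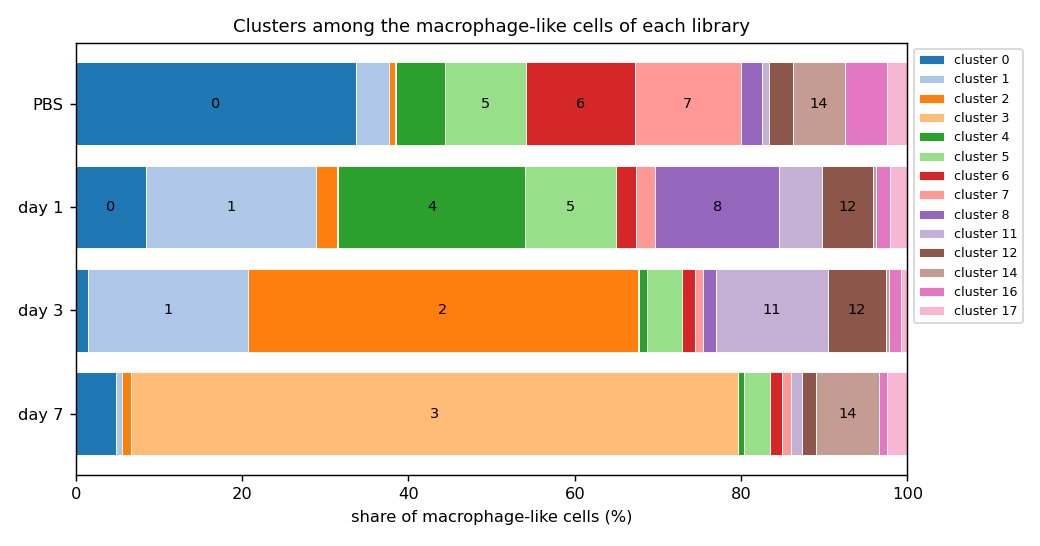
Share of the macrophage-like cells of each library (x axis, percent) that fall in each of the 14 macrophage-like clusters, 1 bar per library. Cluster 0 leads in the PBS library with 33.7%, cluster 4 on day 1 with 22.5%, cluster 2 on day 3 with 46.9% and cluster 3 on day 7 with 73.0%.

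On day 1 after cisplatin, p53 target genes were higher and mitotic genes lower in the library than after PBS. Cdkn1a (ENSMUSG00000023067; mm10 chromosome 17, 29090976 to 29100727), a p53 target that halts the cell cycle, stood at 292 CPM in the PBS library and at 691 CPM in the day 1 library, a log2 ratio of 1.24 (1.21 to 1.27). Phlda3 had a log2 ratio of 2.51, Trp53inp1 of 2.41 and Eda2r of 1.97, and Mdm2, the brake on p53, of 0.97 (0.92 to 1.02). The median of the p53 list was 0.92 over 30 members, above all 10000 random lists, with 22 members higher and 0 lower. Plk1, a mitotic kinase, had a log2 ratio of -2.48, Ccnb2 of -2.33, Cdkn3 of -2.22, Cdca3 of -2.10 and Birc5 of -2.00. The G2M list stood at -1.26 and the S phase list at -0.76, both below all random lists. Mcm5, Mcm6 and Mcm7 of the replication helicase lay between -1.16 and -1.08. These cell cycle values can also follow the mix of cells. Clusters 6 and 14 have cell cycle genes among their leading genes. They held 893 and 428 of 7425 PBS cells and 128 and 17 of 6841 day 1 cells. The summed CPM of the G2M list in clusters 9 and 15 was 3473 and 1443 after PBS and 3465 and 1336 on day 1. In clusters 0 and 5 it was 891 and 1283 after PBS and 749 and 945 on day 1.

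Gzmf, Gpihbp1 and Ngp were among the highest genes in the day 1 ranking. Gzmf, Gzmd and Gzme, granzymes of activated cytotoxic cells, gave 2950, 979 and 568 UMIs on day 1 and 3, 5 and 3 UMIs in the PBS library, and the ratio of Gzmf was 752 (257 to 3648). The endothelial genes Gpihbp1, Igfbp3 and Tmem252 were 52.1, 47.7 and 71.9 times higher, and the neutrophil genes Ngp and Camp were at least 52.2-fold and 26.8-fold higher, with 0 counts after PBS. No list of endothelial or neutrophil genes was tested. The endothelial-like cluster, whose cells a CD45+ gate should leave out, had 22 cells on day 1 and 4 after PBS. Thy1, Il7r and Ptprc had log2 ratios of 1.88, 1.87 and 0.46. Gata3, Tbx21, Eomes and Ifng, which the lymphoid clusters express, stood at 1.62, 2.18, 2.24 and 1.62. The MHC class II genes H2-Aa and H2-Eb1, used to present antigen to CD4 T cells, were both at 1.85. The heat shock genes Hspa1b and Hspa1a were at 1.36 and 1.05. Of the 15 members of their list 6 were higher and 0 lower, with a median of 0.56 (-0.01 to 0.95). Cxcl10, a chemokine that attracts T cells, lay at -0.07 (-0.11 to -0.04), and the type I interferon list had a median of 0.39.

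On day 3 after cisplatin, interferon-induced genes were far higher in the library than after PBS. Isg15 (ENSMUSG00000035692; mm10 chromosome 4, 156199424 to 156200818), a ubiquitin-like antiviral protein, had 4845 UMIs after PBS and 37793 UMIs on day 3, a log2 ratio of 3.62. Ifit1bl1 stood at 4.58, Slfn1 at 3.97 and Isg20 at 3.69. The type I interferon list had a median of 2.30, above all 10000 random lists, with 42 of 43 members higher. Genes induced by interferon-gamma followed, with Cd274, which encodes the checkpoint ligand PD-L1, at 3.83, Gbp4 at 3.50 and a list median of 2.17. Cxcl10 had a log2 ratio of 2.23 (2.20 to 2.26), and Cxcl9 and Ccl5 were at 2.39 and 3.69. H2-Eb1, H2-Aa, H2-Ab1 and Cd74 lay between 2.98 and 3.35.

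Ly6c2 and Gzmf were among the highest genes in the day 3 ranking. Ly6c2, a marker of inflammatory monocytes, was at 6.55 (6.36 to 6.75), Plac8 at 5.25 and Slfn4 at 4.71, and no list of monocyte genes was tested. Gzmf, Gzmb and Gzmc were at 10.07, 4.90 and 4.61, Tbx21 at 3.62 and Ifng at 3.31 (3.13 to 3.50), with a cytotoxic list median of 3.41. Il17a stood at 3.74 with 236 UMIs on day 3 and 28 after PBS. Cdkn1a was at 1.87 and Mdm2 at 1.58, and the p53 list median was 0.96. Cenpf, Hmmr and Cdkn3 of the G2M phase were at -2.96, -3.00 and -2.96, and the G2M and S lists at -1.74 and -0.97. These cell cycle values can also follow the mix of cells, as on day 1. Among the lowest genes were Mcpt2, a mast cell protease, at -4.47, Cspg4 at -3.16 and Hpgd at -3.13, which lead PBS-rich macrophage clusters. Hspb1, Hspa1b and Hspa1a were at -2.06, -1.16 and -1.05.

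On day 7 after cisplatin, Prg4, Col1a1 and haemoglobin genes were among the highest in the library, and several mast cell genes had no UMI in it. Prg4, Col1a1, Thbs4 and Sfrp2, which fibroblasts and joint or connective tissue cells secrete, had log2 ratios of 7.22, 4.97, 5.12 and 5.34. No list of such genes was tested, and cluster 18, with Col1a1 among its leading genes, held 0.998% of the day 7 cells and 1.52% of the PBS cells. Hba-a1, Hba-a2 and Hbb-bs of haemoglobin stood at 5.88, 5.25 and 5.69. Cxcl12, Cyr61 and Spry2 were at 4.44, 4.26 and 3.998. Mcpt4 gave 0 UMIs on day 7 and 2105 after PBS, and Mcpt2, Cpa3 and Tpsb2 were also at 0. A list of mast cell genes was not tested. Against the floor of 3 counts Mcpt4 was at least 213-fold lower. Il17a and Il13 had 0 UMIs, beside 28 and 19 after PBS.

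Of the 25 members of the cytotoxic list 21 were higher on day 7 and 0 lower. Thy1 was at 2.28 (2.11 to 2.46), Nkg7, Xcl1 and Ccl5 at 3.07, 2.89 and 2.36, and Tbx21 and Eomes at 2.54 and 2.34, while Il7r was at -0.60, Cxcr6 at -0.27 (-0.60 to 0.05) and Ifng at 0.14 (-0.21 to 0.47). The Thy1 value is not lymphoid alone. In the collagen-led cluster 18 Thy1 stood at 599 CPM in 27 day 7 cells and at 97.0 CPM after PBS. In group 1 ILC-like cells it stood at 286 CPM on day 7 and 170 CPM after PBS. Cdkn1a was at 0.82 and Mdm2 at -0.56 (-0.66 to -0.45), on opposite sides of 0, and the p53 list median was 0.38 with 12 of 28 members higher and 2 lower. The type I interferon list was at 0.53 and Cxcl10 at -0.65. Mki67, a mark of dividing cells, was at -2.08, and the G2M and S lists at -0.64 and -0.35. These cell cycle values can also follow the mix of cells. The ribosomal protein gene Rplp1 was at -1.26, and S100a4 at -2.21.

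**Figure D4:**
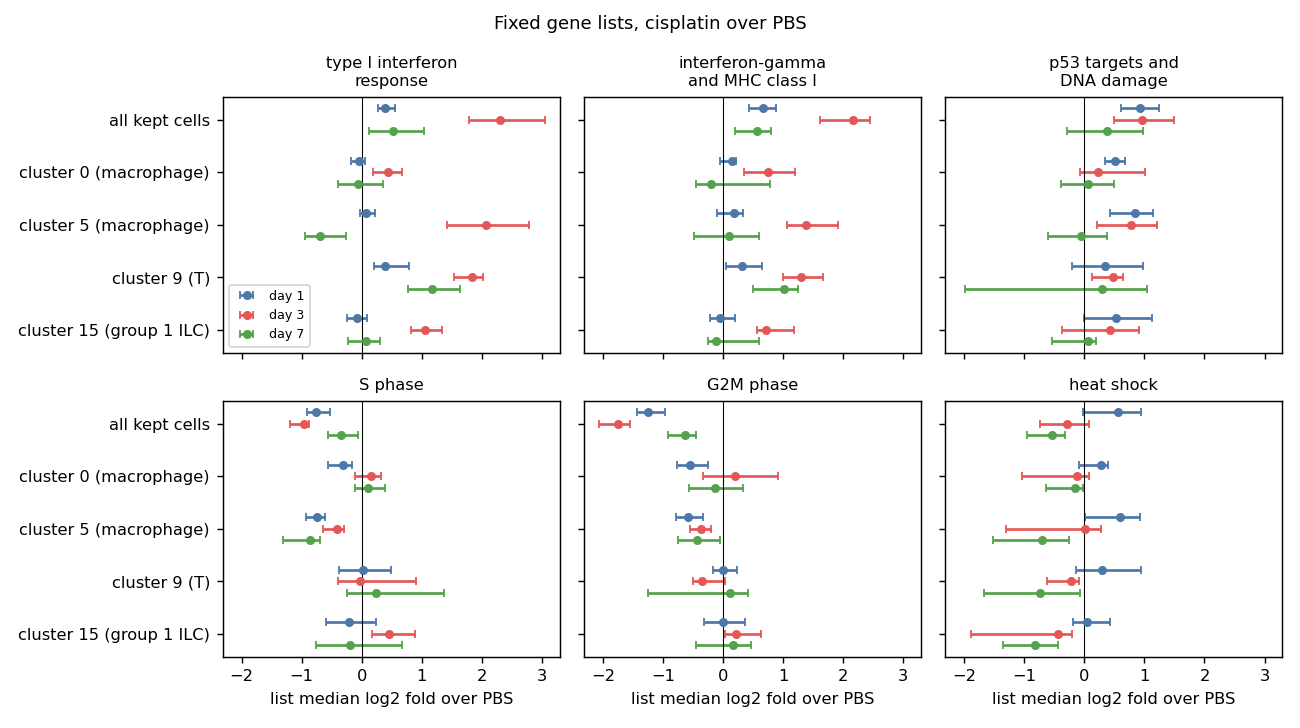
Median log2 ratio over PBS (x axis) of 6 fixed gene lists in all kept cells and in clusters 0, 5, 9 and 15 (y axis), for the day 1, day 3 and day 7 libraries. Bars are the order-statistic intervals over list members. The type I interferon list reaches 2.30 on day 3 over all kept cells and 1.05 in cluster 15.

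The medians of the other fixed lists differed in size and direction. Over all kept cells they also follow the mix of cells, in which the T-like clusters together made up 3.74%, 14.9%, 19.2% and 5.47% of the PBS, day 1, day 3 and day 7 libraries. For days 1, 3 and 7 over all kept cells, they were 1.59, 2.37 and 1.08 for MHC class II, 1.70, 3.41 and 2.33 for cytotoxic effectors, and 1.28, 1.87 and 0.70 for type 3 effectors. Within cluster 15 these lists were at -0.97, 0.77 and -1.25, at -0.21, 0.58 and 0.20, and, with 3 members, at -0.15, -0.53 and -0.22. Its day 1 MHC class II median turned to 0.21 with doublets kept. In its cells with at most 1% of UMIs from macrophage markers that median was 1.56, and on day 7 H2-Aa and H2-Ab1 were at 1.53 and 1.78. Over all kept cells, type 2 effectors stood at 1.01, 1.24 and 0.86, receptors that inhibit or co-stimulate at 1.79, 2.47 and 1.02, and cytokine receptors of ILCs at 1.37, 1.77 and 0.56. Chemokines were at 0.58, 1.45 and 0.01, chemokine and homing receptors at 0.65, 1.06 and -0.08, and tissue residency genes at 0.62, 0.97 and 0.27. NF-kB genes were at 0.45, 1.12 and 0.14, immediate-early genes at 0.35, 0.82 and 0.59, apoptosis regulators at 0.32, 0.58 and 0.08, and interferon-gamma with MHC class I genes at 0.67, 2.17 and 0.56. Heat shock genes were at 0.56, -0.28 and -0.54, glycolysis and hypoxia at 0.11, 0.15 and -0.22, and oxidative phosphorylation at -0.30, -0.33 and -0.21. Lipid uptake was at 0.14, -0.17 and -0.48, TGF-beta response at 0.29, 0.10 and 0.06, and ribosomal proteins at -0.18, -0.38 and -0.34. DESeq2 scaling would move the day 1 values over all kept cells by -0.13, those of cluster 15 by -0.083 and those of cluster 0 by 0.034. TMM would move the day 3 values of cluster 0 by -0.12 and the day 7 values of cluster 5 by -0.14.

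Within the group 1 ILC-like cluster 15, the day 3 library held more Gzmb, Gzmc and interferon-induced RNA than the PBS library. The cluster has 92, 152, 135 and 126 cells in the PBS, day 1, day 3 and day 7 libraries, with 335501, 1415774, 1053907 and 569543 UMIs. Gzmb (ENSMUSG00000015437; mm10 chromosome 14, 56258838 to 56262260), which triggers death of target cells, was at 313 CPM after PBS and 2979 CPM on day 3, a log2 ratio of 3.25 (2.97 to 3.55). Gzmc was at 2.61 and the pore-forming gene Prf1 at 1.95. The cytotoxic list had a median of 0.58, with 10 of 25 members higher and 0 lower. Isg15, Oasl1 and Ifi44 stood at 2.60, 2.83 and 2.44, and the type I interferon median was 1.05, above all random lists, with 27 of 43 members higher. Cdkn1a and Mdm2 were at 1.46 and 1.38, Thy1 at 0.92 and Cxcl10 at 1.17, while Ifng was at 0.12 (-0.11 to 0.35) and Tbx21 and Eomes at 0.36 and 0.53, with intervals that include 0. Among the lowest genes, ranked by the bound nearer to 1, were Hspa1a and Hspa1b at -3.20 and -3.12. Fcrls and Cx3cr1, among the leading genes of macrophage-like cluster 0, were also low, at -3.18 and -3.54.

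On day 1 the p53 targets Cdkn1a and Mdm2 were higher in the same cluster than after PBS. Cdkn1a and Mdm2 were at 0.96 (0.64 to 1.28) and 1.12 (0.46 to 1.87), and the p53 list median was 0.52, at percentile 98.2, with 4 of 22 members higher and 0 lower. Of the 27 members of the cytotoxic list 3 were higher and 6 lower. Xcl1 and Gzma were at -0.81 and -0.70, Ifng at -0.92 and Cxcl10 at -0.89. Ifng turned to 0.22 in the cells with little macrophage RNA. Gzmd, Gzmf and Gzme had 92, 89 and 56 UMIs and none after PBS, which makes Gzmd at least 7.27-fold higher. The highest genes, S100a8, S100a9, Cxcl1, Mmp12, Thbs1 and Fn1, are myeloid, and 61.2% of the day 1 cells of this cluster held more than 1% of UMIs from macrophage markers, against 34.8% after PBS. The median doublet score of these day 1 cells was 0.143, with 13217 UMIs, against 0.0365 and 4063 UMIs in the other day 1 cells of the cluster. Across the cluster 68 cells lie within 0.25 points of that 1% limit. MHC class II genes pointed down at -1.27 for H2-Eb1 and -0.99 for H2-Aa, but turned to 1.69 and 2.33 in cells with little macrophage RNA.

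On day 7 Ifng and heat shock genes were lower in cluster 15, and chemokine genes split. Of the 12 chemokine list members 3 were higher and 3 lower, with a median of 0.11 (-0.70 to 0.89). Ccl7, Ccl2 and Ccl12, which attract monocytes, were at 2.83, 2.37 and 2.23, Csf2 at 3.32 (0.65 to 8.71) from 17 UMIs against 1, and Spry2, which dampens growth factor signalling, at 3.99 (3.35 to 4.72). Macrophage RNA was higher too, since 45.2% of the day 7 cells and 34.8% of the PBS cells passed the 1% limit, and Lyz2 stood at 8054 and 4519 CPM. In cells with little macrophage RNA the ratios of Ccl7, Ccl2 and Ccl12 were 1.24, 1.02 and 0.67. Ifng was at -2.17 (-2.57 to -1.78) and Cxcl9 at -3.27. Cdkn1a at 0.25 (-0.11 to 0.62) and Mdm2 at -0.38 (-1.28 to 0.53) have intervals that include 0. Pfn1, Actb and Slc39a1 were at 2.40, 1.82 and 2.88, and Tpt1, Rack1 and AY036118 at -2.05, -2.05 and -3.45. Of these, Pfn1, Actb, Slc39a1, Tpt1 and AY036118 differed the same way in clusters 0, 5, 9 and 19. The heat shock list stood at -0.81, with 9 of 13 members lower, and the type I interferon list at 0.08. Il5, Il13 and Ccl20 had 0 UMIs in the cluster in every library.

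The Foxp3-led cluster 9 also held more interferon-induced RNA on day 3. On day 3 Ifit1, Irf7, Isg15 and Ifitm3 were at 3.28, 2.84, 2.59 and 2.05, Cxcl10 at 2.21, and the type I interferon median was 1.84 on day 3, 0.39 on day 1 and 1.18 on day 7. Tff1 and Penk, secreted peptides that lead this cluster, were low on all days, with Tff1 at -1.63, -3.01 and -3.78 and Penk at -1.90, -1.15 and -1.85. Klrg1 was at -0.92 on day 1. Il7r was at 0.01 and -0.06 on days 1 and 3 and at -1.45 (-1.84 to -1.08) on day 7, and Areg, a tissue repair factor, at -0.50, 0.04 and -1.24. Cdkn1a was at 0.26 (-0.16 to 0.70), 0.47 (0.05 to 0.92) and 0.61 (0.02 to 1.19). Il22 had 12 UMIs after PBS and 0 on the other days.

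On day 1 macrophage-like clusters 0 and 5, compared by number, also differed from PBS in p53 targets and cell cycle genes. Cluster 5 is led by Mmp9, Ctsk, Acp5 and Ocstamp, genes of osteoclast-like cells. In it Cdkn1a was at 1.23 and 1.70 and Mdm2 at 1.00 and 1.46 on days 1 and 3, and Phlda3 at 2.39 on day 1, while on day 7 Cdkn1a was at -0.15 (-0.42 to 0.11) and Mdm2 at -0.94. The p53 list medians were 0.84, 0.77 and -0.06, and on day 1 the S list stood at -0.74 with 27 of 42 members lower. Ccnb2 and Cdkn3 were at -4.30 and -2.86 on day 1. On day 3 Ly6c2, Ccl5, Isg15 and Ifit3 were at 5.34, 3.91, 3.14 and 3.24, with a type I interferon median of 2.07, and Fcrls, Fn1, F13a1 and Cx3cr1 at -3.45, -3.18, -3.21 and -3.01. In cluster 0 the p53 list was at 0.51 on day 1, with 8 of 25 members higher and 1 lower, and the G2M list at -0.54, with 12 of 47 lower. On days 3 and 7 the intervals of both medians include 0. Cdkn1a was at 0.69, 1.08 and 0.74 on the 3 days and Mdm2 at -0.09 (-0.33 to 0.15), 0.22 (-0.48 to 0.84) and -0.31 (-1.01 to 0.31). Phlda3 was at 2.22 on day 1, Cd74, H2-Aa and Cxcl9 at 2.08, 2.22 and 2.07 on day 3, and the type I interferon median on day 3 was 0.44. Fn1 and Spp1, matrix proteins of tumour macrophages, were at -1.65 on day 1 and -2.25 on day 3.

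The share of cells with cell cycle transcripts depended on the UMI minimum. After thinning, 69.2% of cells in the PBS library (68.1 to 70.3%), 58.8% on day 1 (57.6 to 60.0%), 61.2% on day 3 (59.7 to 62.7%) and 56.7% on day 7 (54.6 to 58.7%) held at least 3 UMIs of the S and G2M lists, with 498, 549, 557 and 391 shallower cells left out. With at least 5 UMIs the shares were 42.5%, 26.4%, 29.3% and 31.1%, so day 7 then lay above day 1. Free RNA was not removed from these counts, and they are not shares of dividing cells. At the minimum of 3 UMIs, macrophage-like cluster 0 gave 56.2%, 46.0%, 55.0% and 54.3%, cluster 5 gave 73.3%, 54.3%, 60.7% and 52.9%, and cluster 9 gave 90.7% (79.7 to 96.9%), 94.5% (90.3 to 97.2%), 82.3% (76.0 to 87.5%) and 78.6% (59.0 to 91.7%). In cluster 9 only 54, 199, 186 and 28 cells were deep enough, and 68, 207, 88 and 26 were left out. Group 1 ILC-like cells gave 89.4% (79.4 to 95.6%), 66.2% (57.8 to 73.9%), 81.1% (73.2 to 87.5%) and 67.6% (57.7 to 76.6%), which became 51.5%, 31.7%, 51.2% and 38.2% at 5 UMIs.

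Several effector and receptor genes of ILC2 and ILC3 were scarce and lay mostly in T-like or mast-cell-like clusters, which can also hold a few cells of other types. Il23r, a part of the IL-23 receptor, had 145 UMIs in all kept cells, and 69.0% of them lay in the gamma-delta T-like cluster. Il17a had 352 UMIs with 87.8% there, and Il5 had 42 UMIs with 95.2% there. Il22 had 43 UMIs, 48.8% in that cluster and 32.6% in alpha-beta T-like cells. Among lymphoid cells with little macrophage RNA, Il5 was found only in the group of 20 cells with ILC2 markers described under other observations. Of these 20 cells 30% held CD3 genes. Of 116 Il13 UMIs, 63.8% came from mast-cell-like cells, and of 1429 Gata3 UMIs, 56.4% came from alpha-beta T-like cells. Ncr1 and Eomes, with 574 and 430 UMIs, had 86.9% and 65.1% in the group 1 ILC-like cluster. Cd3e, a part of the T cell receptor complex, was detected after thinning in 38.4% of alpha-beta T-like cells, in 2.52% of group 1 ILC-like cells and in 0.486% of macrophage-like cells.

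Set side by side, the 4 libraries did not follow 1 order. Isg15, Ly6c2 and cluster 2 were highest in the day 3 library, Phlda3 had a higher ratio on day 1 (2.51) than on day 3 (2.24), and the share of group 1 ILC-like cells was highest on day 7 at the main setting. With each cell in the class of most detected markers that share was highest on day 3, at 3.90% against 3.18% on day 7, and at Leiden resolution 0.5 the class had 0 cells. The labels give no day for the PBS library.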

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

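All tests of explanations below were chosen after the results were seen, except 2 of the day 3 interferon pattern, the test of another mix of cell types and the test of free RNA from cluster 2. The 5 values of the first paragraph were picked out after they were seen, because they lie above the PBS library.

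Cluster 19, unnamed and led by Fst, Dlk1, Cdkn2a and Hmga2, held 4.07% of the day 7 cells and 0.902% of the PBS cells. Ptprc, which encodes CD45 of the sort gate, was detected in 3.49% of its thinned cells, against 49.8% of macrophage-like cells. Of its thinned day 7 cells 100% held at least 3 cell cycle UMIs. Cluster 21, unnamed, with Foxp3 and Ctla4 among its leading genes and macrophage markers in most cells, held 2.18% on day 1 and 1.04% on day 7, against 0.162% after PBS. Its median doublet score of 0.177 was the highest of the 24 clusters, with a median of 8921 UMIs against 2212.5 in cluster 9, so it may hold leftover doublets. Haemoglobin RNA stood at 153 CPM on day 7 and 3.27 CPM after PBS, with 273 CPM in cluster 3 and 2.64 CPM in alpha-beta T-like cells. Barcodes with over 10% mitochondrial counts made up 28.9% of the day 1 library and 18.9% of the PBS library. The cause of these values was not tested.

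Most kept cells of every library were macrophage-like, although the labels describe a sort for innate lymphoid cells. If these were lymphoid cells with free macrophage RNA, their Thy1 and Il7r RNA per UMI should come near that of the lymphoid clusters, but the highest ratio of the 4 libraries was 0.128. If they were droplets with a macrophage and a gated lymphoid cell, they should hold as many of these UMIs as a lymphoid cell, but the highest ratio was 0.154. Macrophages that passed the gate because they express its genes stay open, because transcripts do not measure surface protein. A Thy1 or Il7r UMI was seen in up to 14.6% of thinned macrophage-like cells (day 3). Of those day 3 cells 13.6% held Il7r but only 1.09% held Thy1, and the gate needs both proteins. No biological explanation was tested.

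Many genes differed between the day 7 and PBS libraries, among them Actb at 4.03-fold, Pfn1 at 5.12-fold and Slc39a1 at 7.86-fold, 3 genes picked after their values were seen. Gm42418, picked likewise, was 10.1-fold lower on day 7 over all kept cells. Inside clusters 0, 5, 9, 15 and 19 it was 6.09 to 14.6-fold lower. Barcodes with over 10% mitochondrial counts made up 4.53% of the day 7 library and 18.9% of the PBS library. Genes that differ from PBS inside macrophage-like cluster 0, not over all kept cells, were then followed in clusters 5, 9, 15 and 19. The share of them that differ the same way there had a lowest value of 59.3% on day 7. The shares were 19.4 to 49.2% on day 1 and 35.2 to 41.6% on day 3, where cluster 19 has only 6 cells. Most of the remaining day 7 genes were counted in neither direction. Those that differed the opposite way on day 7 were 18 of 682, 10 of 236, 27 of 432 and 14 of 581 in clusters 5, 9, 15 and 19. On day 1 they were 18 of 315, 17 of 124, 28 of 125 and 37 of 160. On day 3 they were 11 of 382, 16 of 230, 30 of 274 and 40 of 222. A difference of the whole library cannot be told apart from an effect of treatment or time, since 1 library is 1 batch. A few abundant genes are excluded as the whole cause, because the 12 genes with the largest gain would move all others by only -0.0943 log2, a test redefined after its first form had used scarce genes (-0.00077). RNA of red blood cells makes up 0.0153% of the day 7 counts, too little to move other genes.

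Type I interferon genes were higher in the day 3 library over all kept cells. Another mix of cell types in the day 3 library may add to this, because the median was at least 0.5 of that over all cells in 2 of clusters 0, 5, 9 and 15, with ratios of 0.190, 0.901, 0.799 and 0.456. Different shares of the clusters alone are not the whole cause. Inside 4 of the 4 clusters the median lay above 0 and above random lists. In cluster 0, though, the summed CPM of the list was 3968 on day 3 and 4068 after PBS. A change of mix inside a cluster, or leftover doublets there, was not tested and stays possible. Free RNA from the monocyte-like cells of cluster 2 would bring interferon and monocyte genes in the proportion seen there, but in cluster 9 the proportion was 6.34 times higher. That result covers cluster 9 and the monocyte genes Chil3 and Ly6c2 only. Free RNA was not tested in clusters 0, 5 and 15, nor from other source cells. It stays possible there, and in cluster 5 Ly6c2 was also higher on day 3. An effect of cisplatin stays a hypothesis, because day, batch and treatment coincide.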

How the results depend on the processing

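The values of cells with little macrophage RNA, clusters 0, 5 and 9, and doublet removal at the loading rate come from settings chosen after the data were seen. Of the alternatives run, 2729 list medians stayed within their interval, 113 moved beyond it and 9 called ones changed sign, and for single genes these numbers were 5249, 944 and 25. As sums of clusters, the main shares for the PBS, day 1, day 3 and day 7 libraries were 91.7%, 74.9%, 74.5% and 83.7% for macrophage-like cells and 3.74%, 14.9%, 19.2% and 5.47% for T-cell-like cells. With each library clustered on its own the T-cell-like share of day 7 lay above that of day 1, and with a class per cell the group 1 ILC-like share of day 3 lay above that of day 7. Class shares moved in 55 cases and stayed in 41. Values of cycling cells moved in 16 cases. Where a value below differs from the one reported, the cause was not tested. The group 1 ILC-like class has 0 cells where no cluster met its naming rule. Clustering without cell state genes and TMM scaling moved none of the leading results. Some members gave no value under thinning, stricter filters or higher minimums, because too few members or no counts in 1 library remained. Depth limits cluster 15, where 2-fold differences were recovered for 77.2 to 90.3% of simulated genes and 1.5-fold differences for 42.6 to 59.7%.

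With predicted doublets kept the share of macrophage-like cells was 90.7% (PBS), 72.8% (day 1), 72.8% (day 3), that of T-cell-like cells was 2.45% (PBS), 8.22% (day 1), 12.6% (day 3), 3.83% (day 7), that of group 1 ILC-like cells was 1.55% (PBS), 2.65% (day 1). The log2 ratios for day 1 in cluster 15 were MHC class II list 0.21, H2-Eb1 0.18, H2-Aa 0.29, H2-Ab1 0.24, Mki67 -0.62. Those for day 3 in cluster 15 were type I interferon list 1.34. With at least 1000 genes and at most 5% mitochondrial counts the share of macrophage-like cells was 93.8% (PBS), 78.5% (day 1), that of T-cell-like cells was 1.54% (PBS), 10.1% (day 1), 13.8% (day 3), that of group 1 ILC-like cells was 0.862% (PBS). With every barcode kept the share of macrophage-like cells was 78.2% (PBS), 52.9% (day 1), 62.1% (day 3), 79.7% (day 7), that of T-cell-like cells was 2.79% (PBS), 8.66% (day 1), 12.2% (day 3), 4.29% (day 7), that of group 1 ILC-like cells was 0.999% (PBS), 1.63% (day 1). With each cell in the class of most detected markers the share of macrophage-like cells was 97.2% (PBS), 94.0% (day 1), 86.4% (day 3), 92.6% (day 7), that of T-cell-like cells was 0.741% (PBS), 1.90% (day 1), 5.68% (day 3), 2.29% (day 7), that of group 1 ILC-like cells was 0.943% (PBS), 1.67% (day 1), 3.90% (day 3), 3.18% (day 7).

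With each library clustered on its own the share of macrophage-like cells was 76.7% (day 1), 68.1% (day 3), 75.2% (day 7), that of T-cell-like cells was 5.91% (day 1), 9.99% (day 3), 6.73% (day 7), that of group 1 ILC-like cells was 0% (day 1). At Leiden resolution 2 the share of T-cell-like cells was 2.42% (PBS), 7.28% (day 1), 8.21% (day 3), 2.40% (day 7). At Leiden resolution 0.5 the share of T-cell-like cells was 12.4% (day 1), 10.8% (day 3), 4.14% (day 7), that of group 1 ILC-like cells was 0% (PBS), 0% (day 1), 0% (day 3), 0% (day 7). At full depth the share of cycling cells was 94.4% (PBS), 94.9% (day 1), 91.1% (day 3), 82.6% (day 7).

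With at least 5 cell cycle UMIs the share of cycling cells was 42.5% (PBS), 26.4% (day 1), 29.3% (day 3), 31.1% (day 7). With DESeq2 size factors the log2 ratios for day 1 in all kept cells were type I interferon list 0.26. With means of per-cell CPM the log2 ratios for day 1 in all kept cells were Ccl20 -0.39. Those for day 1 in cluster 15 were MHC class II list 0.00702, H2-Aa 0.00387, H2-Ab1 0.0891. With thinned cells the log2 ratios for day 3 in all kept cells were Il5 -0.11. Those for day 7 in all kept cells were Lta -0.00312. Those for day 1 in cluster 15 were inhibitory and co-stimulatory receptors list -0.11. Those for day 3 in cluster 15 were G2M phase list -0.0963. Those for day 7 in cluster 15 were p53 list 0.58, Entpd1 0.22. Those for day 1 in cluster 9 were Cxcl10 0.12.

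In cells with little macrophage RNA the log2 ratios for day 1 in cluster 15 were MHC class II list 1.56, lipid uptake and storage list -0.29, Ifng 0.22, H2-Eb1 1.69, H2-Aa 2.33, H2-Ab1 1.43, Bax -0.35. Those for day 3 in cluster 15 were type I interferon list 0.79, immediate-early list -0.0223, Fabp5 0.0468, Bcl2l11 -0.0477. Those for day 7 in cluster 15 were H2-Aa 1.53, H2-Ab1 1.78, Gpr183 1.25, Rel 0.0369, Atf3 0.12, Pdk1 0.27. Those for day 7 in cluster 9 were Cxcl10 -0.93. With list members of at least 100 UMIs the log2 ratios for day 1 in cluster 15 were inhibitory and co-stimulatory receptors list -0.074. Those for day 7 in cluster 15 were p53 list 0.22. With list members of at least 1 UMI the log2 ratios for day 3 in cluster 15 were G2M phase list -0.00399.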

Other observations

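The grouping of lymphoid cells described here was made after the data were seen. Cells with at most 1% of UMIs from macrophage markers were clustered again, and 1 group of 140 cells had Il23r in 16.4% of cells, but CD3 genes in 85.7%. Within it, 20 cells had 9 ILC2 markers at 3-fold or more (Gata3, Il1rl1, Il5, Il13, Areg, Klrg1, Hs3st1, Arg1 and Calca), with Gata3 in 45% of cells, Il5 and Il13 in 15% each and CD3 genes in 30%. They came as 8, 9, 2 and 1 cells from the PBS, day 1, day 3 and day 7 libraries, too few to compare. Another 30 cells, led by Ifit1, Cxcl10 and Irf7, came as 0, 1, 27 and 2.

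Of 3323 Il1rl1 UMIs, which encode the IL-33 receptor ST2, 65.7% lay in the unnamed clusters. Of 3449 Cxcr6 UMIs, 46.3% lay in gamma-delta T-like and 41.6% in alpha-beta T-like cells, and 1.16% in group 1 ILC-like cells.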
